A study of Oryctolagus cuniculus with 36 samples.

How the data were processed

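RNA sequencing of rabbit liver was analysed from 1 table of gene-level values for 36 libraries, 12 each of WT, FA and FK. The labels state that livers were treated with trypsin and extracted with TRIzol, and that libraries were made with a TruSeq RNA kit. They do not state whether the strand of the RNA was kept, so genes that overlap on opposite strands are uncertain. The values are estimated counts, whole numbers as deposited. The submitters' processing notes name Salmon 0.14.1. Its role in making the table, the genome build and the rounding are not given in the sources used here. The table lists 23394 genes, of which 8019 carry only a LOC identifier, and 765 of these have another symbol in the RefSeq gene table of assembly mOryCun1.1, which was used for names and neighbouring genes alone.

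Library totals ran from 11.7 to 22.5 M counts, and each library held 15581 to 16301 genes with a count. At this depth FAH was measured by 120 to 550 counts per library in FA and FK and by 2910 to 4633 in WT. Albumin took 10.55% to 21.19% of a replicate's counts. Titles place the libraries in 9 sets of 4. Within sets, Pearson's r of log CPM was 0.980 to 0.990 (median 0.987, 54 pairs), against 0.818 to 0.971 between sets of a group (median 0.96, 144 pairs). Counts within sets varied more than sampling noise. Over genes, the chi-square per degree of freedom had a mean of 4.625 to 24.39 and a median of 1.547 to 4.056. The biological coefficient of variation was 6.71% to 13.5%, against 45.2% between the summed replicates. The 4 libraries of a set were therefore not treated as runs of 1 library, nor, with no label that makes them separate animals, as 4 replicates. Their counts were summed, which gave 3 replicates per group.

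Before the data were examined, the tests, the gene lists, the alternatives and the rule for naming genes were fixed. The 9 replicates were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr by group and quasi-likelihood F tests, which left 14939 genes. The prior had 2.89 degrees of freedom beside 6 residual ones. A gene was called, and is said to have risen or fallen, at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. CPM values are counts per M counts after TMM scaling, given as mean ± SD of 3 replicates, and changes are fitted log2 differences with standard errors. A group with 0 counts was set at a floor of 3 counts over the group, and with 1 to 3 counts a ratio is given with its exact 95% counting interval.

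Of 36 fixed gene lists, with 762 genes of which 663 matched a gene of the table, 35 had at least 3 tested members. The list of mitochondrially encoded genes had 0 and was left out. Lists were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the 35 lists of a comparison. Beside it stand camera with a correlation estimated for each list, fry, and the number of members called over all genes and when adjusted over the list alone. Genes were named by rule. FAH came first. Next came, among called genes with a symbol, a mean of at least 10 CPM in the higher group and no overlap between the replicates, the 6 largest rises and 6 largest falls. Then followed up to 3 called members of each list that camera called, the tyrosine breakdown genes, and the member with the smallest p of a list without calls. Genes that the rule named but that are not reported here were not replaced by others. Genes outside the rule were chosen after their values were seen and are marked so. Genes with similar copies, such as the cytochrome P450 and S100A families, are uncertain, since estimated counts divide shared reads among them.

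The procedure was tested on simulated data with 200 changed genes in each comparison. It recovered 2% of 2-fold and 87% of 8-fold changes with 0 false calls for FK and WT, 1% and 86% with 4 for FA and WT, and 2% and 78% with 5 for FA and FK. Changes of 2-fold are thus mostly out of reach at this spread. For calls shared by comparisons with a common group, 20 simulations of unchanged groups were run, and these held at most 1 call in either comparison.

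Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a filter of at least 1 CPM in 3 replicates, a fit of only the 2 groups compared, a 2-fold minimum, the set number as a replicate block, the 36 libraries as separate replicates, limma-voom on 36 libraries with the set as a random block (consensus correlation 0.791), library 1 of each set alone, and each replicate left out in turn. Counting list members without FK replicate 3 was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.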

Results

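RNA was sequenced from the livers of rabbits in a series on CRISPR/Cas9 correction of hereditary tyrosinemia type I in newborn animals. The disease is the loss of fumarylacetoacetate hydrolase (FAH), the last enzyme of tyrosine breakdown. The sample titles form 3 groups, wild type (WT) and the libraries labelled FA and FK, whose abbreviations the labels do not spell out. All 36 samples carry the same disease description, so the groups rest on the titles alone. Each group holds 3 numbered sets of 4 libraries. Totals ran from 14.2 to 18.7 M counts per library in WT, from 15.1 to 22.5 M in FA and from 11.7 to 16.1 M in FK. The labels do not say that the 4 libraries of a set came from separate animals, and their log counts correlated at a median r of 0.987 across genes within a set against 0.96 between sets of a group. The 4 were summed to 1 replicate of 53.2 to 78.6 M counts, so that n = 3 per group throughout. The labels do not tie the sets to separate animals either, so p-values measure only the spread between these sets, which may be technical.

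FAH, the gene of the disease, separated WT from both other groups. Its level was 242 ± 26.9 CPM (counts per M counts; mean ± SD, n = 3) in WT, 23.4 ± 3.27 in FA and 14.3 ± 2.28 in FK, or 9.66% and 5.90% of the WT mean. The highest FA or FK replicate, at 25.8 CPM, lay far below the lowest WT replicate, at 217.5 CPM. Both differences from WT passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at a log2 change of -4.08 (SE 0.23, adjusted p = 0.000466) in FK and -3.37 (SE 0.22, adjusted p = 0.00183) in FA. FA exceeded FK by 0.71 log2 units (SE 0.21; 95% interval 0.25 to 1.18), and the lowest FA replicate (19.6 CPM) lay above the highest FK replicate (16.4 CPM). That last difference did not pass the adjusted threshold (adjusted p = 0.119), while DESeq2 (0.0174) and the fit without FK replicate 3 (0.0336) placed it under 0.05. A 2-fold minimum leaves this difference out by its size. In the other alternatives its adjusted p ran from 2.05e-06 (36 libraries as separate replicates) to 0.309 (without FK replicate 1).

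**Figure D1:**
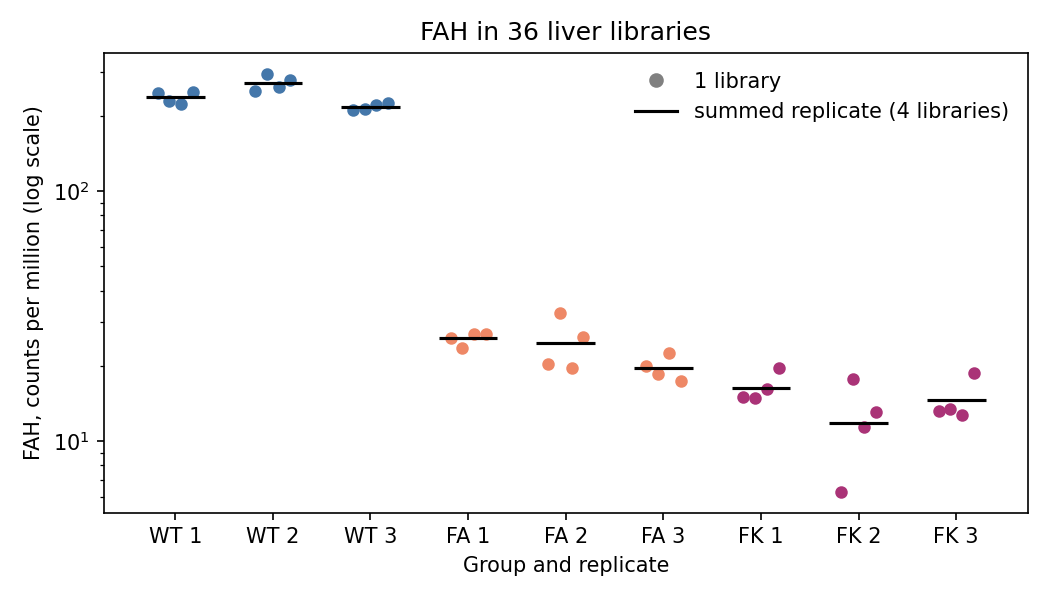
FAH level in CPM (log axis) for each of the 36 libraries, grouped by replicate on the horizontal axis. Points are libraries scaled by the factor of their replicate and black lines are the summed replicates, which lie between 217.5 and 270.7 in WT, 19.6 and 25.8 in FA, and 11.8 and 16.4 in FK.

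The replicates of FK were not alike. FK replicate 3 correlated across genes at r = 0.958 to 0.970 with the FA replicates, but at 0.854 and 0.821 with FK replicates 1 and 2. The first principal component of the 9 replicates, with 56.7% of the variance, placed FK replicates 1 and 2 at 141.2 and 154.2 and the other 7 replicates between -48.2 and -34.4. The next component, with 14.2%, placed the WT replicates between 48.7 and 53.1 and the FA replicates and FK replicate 3 between -52.9 and -27.9. The median of each FK replicate is therefore given beside each list that camera called between FK and WT.

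**Figure D2:**
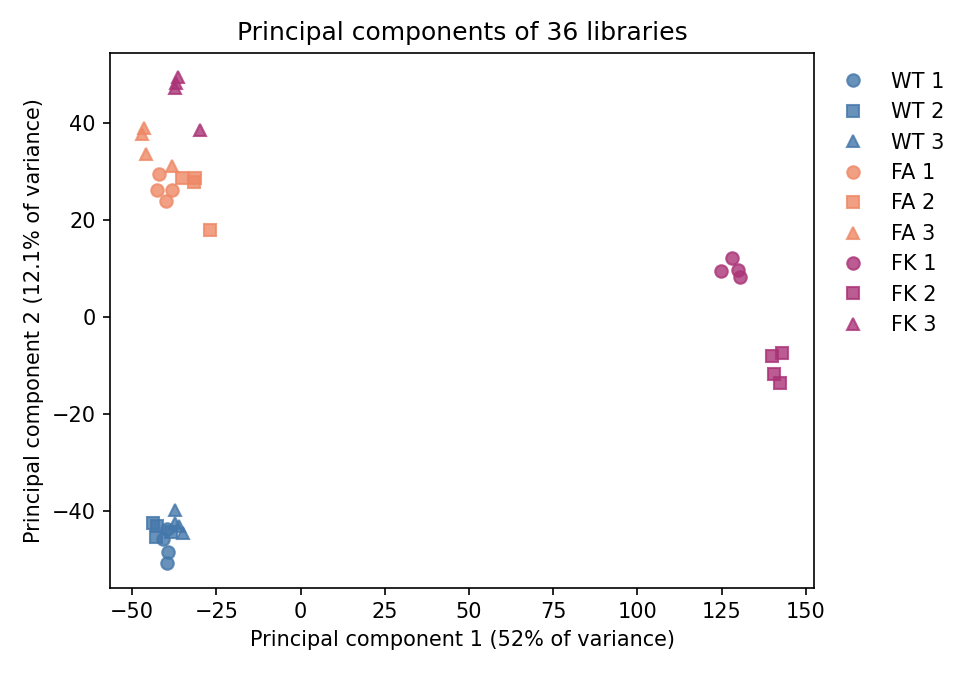
Principal components 1 and 2 of log CPM in the 36 libraries, with colour for the group and marker shape for the replicate. Component 1 (52% of the variance) parts the 8 libraries of FK replicates 1 and 2 from the other 28, and component 2 (12.1%) parts WT from FA and FK replicate 3.

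The comparison of FK with WT asked how the livers labelled FK departed from wild type. Some genes of cholesterol synthesis, lipid synthesis and tyrosine breakdown fell in FK, together with KMO and CYP7A1, while some cell division, fetal liver and p53 response genes rose. None of these 6 lists was called with an estimated correlation (adjusted p of 0.161 to 0.402), and the cell division and fetal liver medians of FK replicate 3 were only 0.28 and 0.20. Of 14939 genes tested, edgeR called 712 at an adjusted p under 0.05, 454 higher and 258 lower in FK. At an unadjusted p under 0.05 there were 4016. The largest rises under the naming rule were those of ELOVL4, NRK, AFP, DUSP9, CYP19A1 and SERPINB7, and among the largest falls were those of MUC15, KMO, ADCY8, CYP7A1 and KRBOX1. AFP, the main plasma protein of the fetal liver, rose from 2.52 ± 1.55 to 1163 ± 1111 CPM (adjusted p = 0.0255). Its log2 change was 8.85, or 7.77 without FK replicate 2 (adjusted p = 0.0549). AFP was not particular to FK. It stood at 973, 68.8 and 519 CPM in FA replicates 1, 2 and 3, without a call between FA and WT, and at 228 in FK replicate 3. The named falls were not particular to FK either. MUC15, KMO, ADCY8, CYP7A1 and KRBOX1 had means of 23.2, 75.7, 14.5, 739 and 27.5 CPM in WT. Their FA means were 0.324, 1.97, 0.675, 129 and 5.48 CPM, without a call between FA and WT. CYP19A1, the aromatase that makes estrogens, rose from 0.118 ± 0.113 to 13.4 ± 8.42 CPM (adjusted p = 0.034). KRBOX1 fell from 27.5 ± 2.59 to 1.22 ± 0.822 CPM (adjusted p = 0.00601), 22.6-fold, or 37.2-fold without FK replicate 3. ELOVL4, which elongates very long fatty acids, had 2 counts over the whole WT group against 2269 in FK, a ratio of 1110 (95% exact interval for counting error 308 to 9210). MUC15 had 2 counts in FK against 4307 in WT, a ratio of 2190 (607 to 18100). It stood at 3.53, 31.9 and 34.1 CPM in WT replicates 1, 2 and 3, a spread that the counting interval leaves out. ELOVL4 and NRK stood at 18.1 and 36.0 CPM in FK replicate 1 and 17.2 and 26.7 in replicate 2, but at 0.0507 and 0.203 in replicate 3.

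Besides FAH, HPD and QDPR of the tyrosine breakdown pathway fell. Of the 8 genes of the pathway 3 were called lower (4 when adjusted over the list alone) and none higher. HPD, the enzyme that nitisinone inhibits, fell from 2342 ± 168 to 716 ± 195 CPM, by 1.71 on the log2 scale (SE 0.34, adjusted p = 0.0382). QDPR, which regenerates tetrahydrobiopterin, fell by 1.21 (SE 0.28, adjusted p = 0.0491). GSTZ1 (-1.16), HGD (-1.01), PCBD1 (-0.73) and TAT (1.05) did not pass, with adjusted p of 0.0609, 0.172, 0.156 and 0.203. The list as a whole, FAH included, ranked lower than other genes by camera (adjusted p = 3.17e-06), with medians of -1.77, -1.01 and -0.74 in FK replicates 1, 2 and 3. Adjusted p = 0.161 with an estimated correlation. Outside the pathway, 4 of 23 genes of other amino acid breakdown were called, 1 higher and 3 lower (4 higher and 6 lower when adjusted over the list alone), in a list that camera did not call (adjusted p = 0.071). KMO, which hydroxylates kynurenine, fell from 75.7 ± 20.5 to 0.383 ± 0.291 CPM (adjusted p = 0.0112), 198-fold, or 348-fold without FK replicate 3. GNMT, a main consumer of S-adenosylmethionine in liver, fell from 2079 ± 111 to 524 ± 93.4 CPM (adjusted p = 0.0241). CTH, which makes cysteine from cystathionine, rose from 62.0 ± 12.2 to 580 ± 391 CPM (adjusted p = 0.0368). In FA the means of KMO, GNMT and CTH were 1.97, 862 and 133 CPM, on the same side of WT as in FK. None of the 3 was called between FA and WT, where KMO had adjusted p = 0.0598 in edgeR.

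Cholesterol and lipid synthesis lists had medians below WT in all 3 FK replicates, and the bile acid list mainly in replicates 1 and 2. Of 19 cholesterol synthesis genes 12 fell and none rose (16 and 0 when adjusted over the list alone), with a median log2 change of -1.80 and per-replicate medians of -2.09, -1.53 and -1.68. Camera gave an adjusted p of 3.57e-16, and adjusted p = 0.266 with an estimated correlation. The identifier LOC100343510, named IDI1 in the RefSeq table, fell from 216 ± 72.9 to 25.6 ± 7.41 CPM (adjusted p = 0.015). NSDHL fell from 157 ± 45.0 to 31.3 ± 6.24 CPM (adjusted p = 0.0198), and FDPS from 166 ± 71.6 to 30.8 ± 6.92 CPM (adjusted p = 0.0263). Of 14 lipid synthesis genes 6 fell and none rose (8 lower and 1 higher when adjusted over the list alone; camera adjusted p = 1.61e-05, and adjusted p = 0.266 with an estimated correlation). Among them were GPAM, the first step of glycerolipid assembly, at -3.23 (SE 0.50; 9.4-fold, or 15.9-fold without FK replicate 3), ACACB at -2.31 (SE 0.42) and the regulator SREBF1 at -1.45 (SE 0.28). The lipid synthesis medians were -1.45, -0.98 and -1.02 in FK replicates 1, 2 and 3. Of 18 bile acid genes 2 fell and none rose (3 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.000757, and adjusted p = 0.402 with an estimated correlation). CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell from 739 ± 178 to 18.2 ± 25.4 CPM, and CYP27A1 from 220 ± 46.1 to 47.9 ± 38.2 CPM. CYP7A1 stood at 2.78, 4.35 and 47.5 CPM in FK replicates 1, 2 and 3 and CYP27A1 at 22.3, 29.5 and 91.8, so that the falls of 40.6-fold and 4.59-fold were 210-fold and 8.56-fold without FK replicate 3. The bile acid medians were -2.24, -2.34 and -0.42 in FK replicates 1, 2 and 3.

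Lists of blood-lineage and proliferation genes had high medians in FK replicates 1 and 2 and not in replicate 3, although TFRC and TYMS were above WT in all 3. Of 30 cell division genes 14 rose and none fell (29 higher and 1 lower when adjusted over the list alone), with a median log2 change of 4.31 and replicate medians of 4.08, 5.33 and 0.28. TYMS, a thymidylate synthase, rose by 2.80 (SE 0.36) and stood at 7.28 CPM in replicate 3 against 1.87 ± 0.482 in WT, the kinesin KIF20A by 4.53 (SE 0.94) and the cyclin CCNE1 by 4.29 (SE 0.91). CCNE1 stood at 5.77, 18.9 and 1.05 CPM in FK replicates 1, 2 and 3. Without replicate 2 the changes of KIF20A and CCNE1 were 3.62 and 2.97 and were not called (adjusted p = 0.0942 and 0.0901). Of 10 neutrophil markers 3 rose (8 when adjusted over the list alone), namely the calcium-binding S100A8, S100A9 and S100A12, and the replicate medians were 2.63, 5.15 and 0.12. S100A9 stood at 577 and 850 CPM in FK replicates 1 and 2, at 8.26 in replicate 3 and at 6.94 ± 2.39 in WT. Of 16 erythroid markers 1 rose, TFRC, the transferrin receptor, from 23.9 ± 4.58 to 218 ± 93.3 CPM (adjusted p = 0.015), with 143 CPM in replicate 3 and 161 ± 71.5 in FA. Adjusted over the list alone 15 rose, and the replicate medians were 5.46, 6.23 and -1.16. Camera called all 3 lists higher in FK, with adjusted p of 2.12e-15 for cell division, 6.35e-05 for neutrophil and 3.17e-06 for erythroid markers, but each had adjusted p = 0.402 with an estimated correlation. Without FK replicate 3, where list members were counted only after the data were seen, 29 of 30 cell division genes, all 11 neutrophil markers and all 17 erythroid markers tested were called higher.

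Drug metabolism, interferon and fetal liver lists also had medians farther from WT in FK replicates 1 and 2 than in replicate 3. Of 28 drug metabolism genes 1 fell, CYP2J1, a member of a family of similar genes whose reads the counting can split (0 when adjusted over the list alone; camera adjusted p = 1.89e-08, and adjusted p = 0.402 with an estimated correlation). Their medians were -3.71, -3.64 and -0.14 in FK replicates 1, 2 and 3, and 23 of 28 were called lower without FK replicate 3. Of 21 interferon response genes 1 fell, STAT2, from 64.6 ± 5.41 to 22.6 ± 10.5 CPM (4 when adjusted over the list alone; camera adjusted p = 2.81e-07, and adjusted p = 0.402 with an estimated correlation). The interferon medians were -2.04, -2.28 and -0.41, and 18 of 21 were called lower without FK replicate 3. Of 13 fetal liver genes 3 rose and none fell (6 when adjusted over the list alone; camera adjusted p = 2.02e-05, and adjusted p = 0.311 with an estimated correlation). The fetal liver medians were 1.98, 3.54 and 0.20 in FK replicates 1, 2 and 3. GPC3, a heparan sulfate proteoglycan, rose from 2.47 ± 0.658 to 145 ± 71.1 CPM in all 3 FK replicates, whereas IGF2BP3, an RNA-binding protein, stood at 10.9 and 17.2 CPM in replicates 1 and 2 and at 0.625 in replicate 3. In contrast, lymphocyte markers were low in replicate 3 too. T and NK cell markers (1 of 15 lower, CD5; 8 lower and 1 higher when adjusted over the list alone) and B and plasma cell markers (1 of 11 lower, MS4A1; 5 lower when adjusted over the list alone) ranked lower by camera. Their adjusted p were 5.6e-06 and 1.82e-05, and for each list adjusted p = 0.311 with an estimated correlation. Their medians in FK replicates 1, 2 and 3 were -2.87, -1.57 and -1.24 for T and NK cells and -1.87, -0.74 and -1.73 for B and plasma cells.

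Some p53 response genes and 2 regulators of the acute phase response rose in FK. The inflammatory signal list (0 of 21 called, also when adjusted over the list alone) and the integrated stress list (2 of 21 higher, 5 when adjusted over the list alone) were not called by camera, with adjusted p of 0.355 and 0.102. Of 21 p53 response genes 4 rose and none fell (9 when adjusted over the list alone; camera adjusted p = 0.00196, and adjusted p = 0.176 with an estimated correlation). CDKN1A, a cell cycle inhibitor, rose from 13.2 ± 2.18 to 44.9 ± 13.8 CPM, TIGAR from 0.730 ± 0.331 to 5.35 ± 0.686 CPM, and EDA2R from 0.237 ± 0.106 to 1.00 ± 0.123 CPM. Their FA means were also above WT, at 36.9, 5.18 and 0.771 CPM, with a call between FA and WT for TIGAR alone. Of 18 acute phase genes 2 rose (6 when adjusted over the list alone; camera adjusted p = 0.0079, and adjusted p = 0.47 with an estimated correlation). Both are regulators of the response, not secreted proteins: STAT3 rose from 137 ± 31.1 to 368 ± 53.2 CPM (adjusted p = 0.0414) and SOCS3 from 5.06 ± 2.29 to 51.3 ± 31.5 CPM (adjusted p = 0.0486). The medians in FK replicates 1, 2 and 3 were 0.81, 0.66 and 0.43 for the p53 list and 1.19, 0.95 and 1.04 for the acute phase list. Both lists lost their camera call without FK replicate 3, at adjusted p of 0.0999 and 0.159, with list medians of 0.74 and 0.97 there against 0.64 and 1.19 with it. None of 27 complement and coagulation genes was called (0 also when adjusted over the list alone), although the list ranked lower by camera (adjusted p = 0.027, and adjusted p = 0.611 with an estimated correlation). The complement medians were -0.54, -1.04 and 0.22 in FK replicates 1, 2 and 3, and 9 of 27 were called lower without FK replicate 3. The member with the smallest p was PROC, at -1.31 (SE 0.40, adjusted p = 0.0803). In all, camera called 15 of 35 lists, 6 up and 9 down, and none with an estimated correlation. Without FK replicate 3, 13 of the 15 were called as well as 2 others, integrated stress (0.00262) and glycolysis (0.0078). With an estimated correlation those 2 had adjusted p = 0.197 and 0.437 without FK replicate 3, where drug metabolism alone of all lists passed (0.00221).

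The count of 712 changed with each replicate left out. It was 5396 without FK replicate 3, but 22 and 57 without FK replicates 1 and 2, 28, 32 and 35 without WT replicates 1, 2 and 3, and 113, 154 and 103 without FA replicates 1, 2 and 3. DESeq2 called 2721, the fit of FK and WT alone 43.

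**Figure D3:**
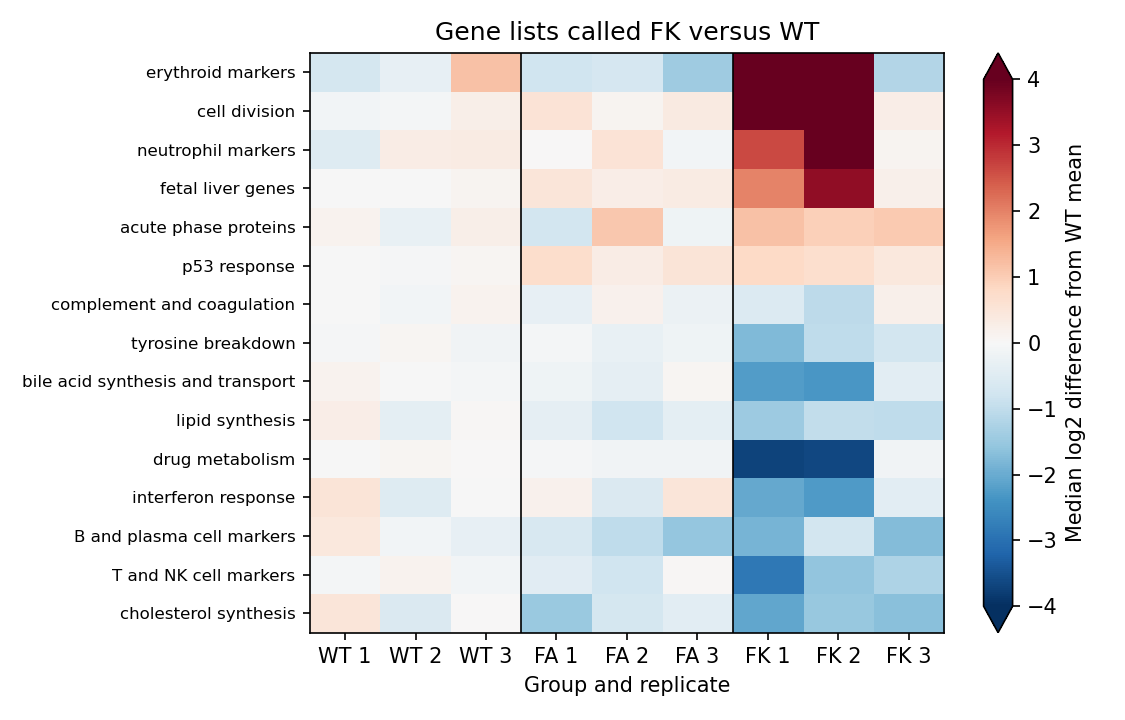
Median log2 difference from the WT mean over the members of each of the 15 gene lists that camera called between FK and WT (rows), in each replicate (columns), with colours clipped at 4. FK replicates 1 and 2 show the erythroid medians of 5.46 and 6.23 and the drug metabolism medians of -3.71 and -3.64, which replicate 3 (-1.16 and -0.14) does not, while cholesterol synthesis lies between -2.09 and -1.53 in all 3.

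**Figure D4:**
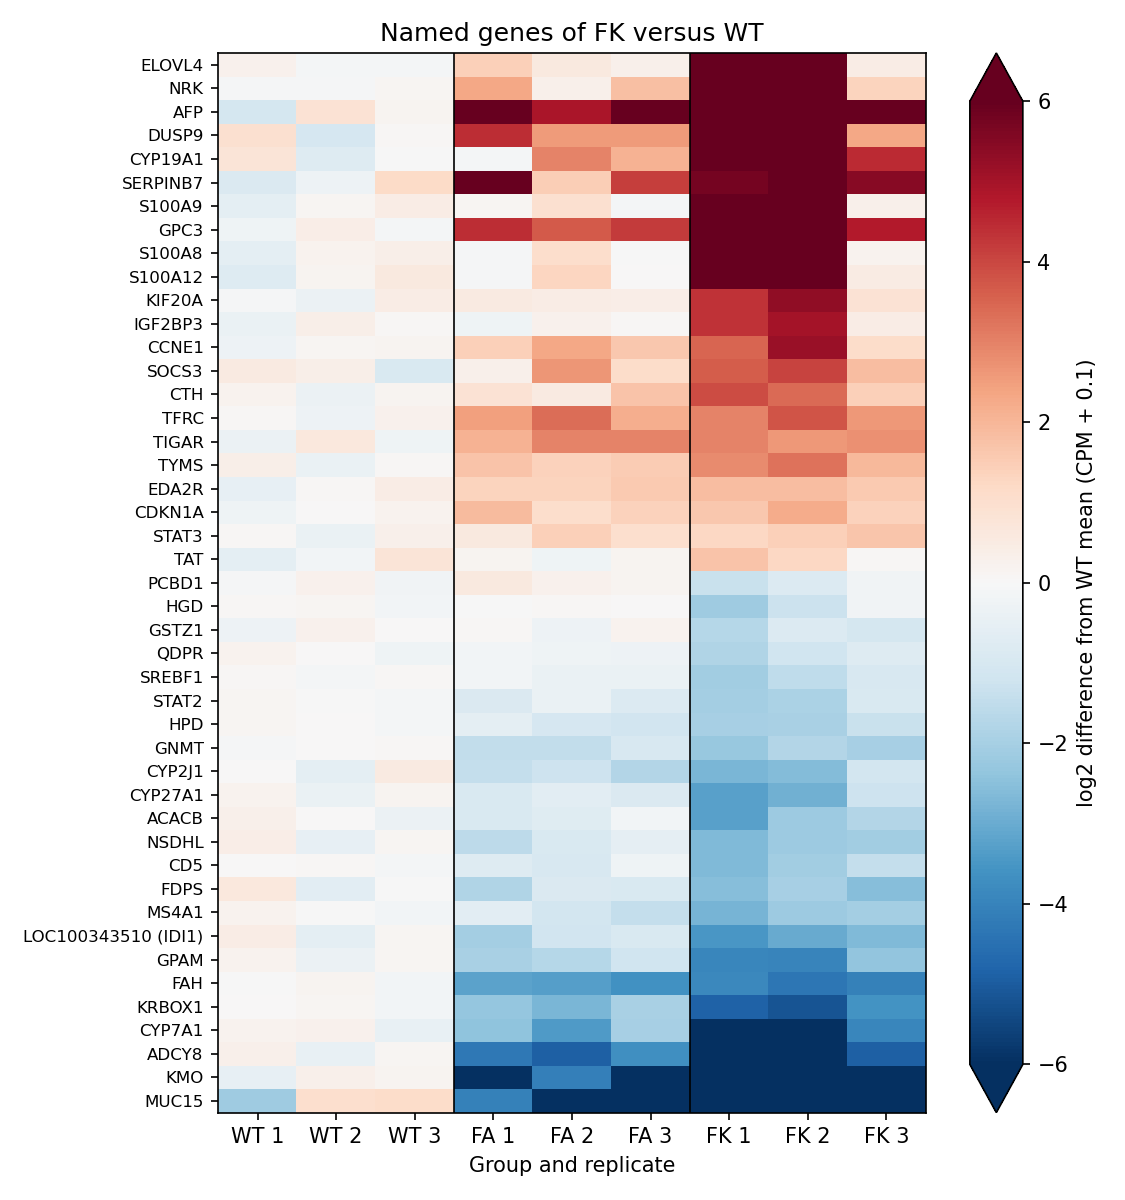
Log2 difference from the WT mean of CPM, after adding 0.1, for 45 genes named between FK and WT (rows) in each replicate (columns), with colours clipped at 6. FAH, KMO and GPC3 differ from WT in all 6 FA and FK replicates, while S100A9 (577, 850 and 8.26 CPM) differs in FK replicates 1 and 2 alone.

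The comparison of FA with WT asked what set the livers labelled FA apart from wild type. Besides FAH, 10 genes fell and 14 rose, 25 calls in all among 14939 genes (1518 at an unadjusted p under 0.05). The spread behind this count was estimated over all 9 replicates, including the unlike FK replicates. Fitting only FA and WT gave 235 calls, and leaving out FK replicate 3 gave 247. The 25 calls therefore do not measure how little FA differed from WT. SCG3, a granin of secretory granules, rose from 0.844 ± 0.317 to 36.1 ± 8.95 CPM, at a log2 change of 5.41 (SE 0.43, adjusted p = 0.004). GPC3 rose from 2.47 ± 0.658 to 44.0 ± 10.6 CPM (adjusted p = 0.0128). FANCD2, of the Fanconi anemia pathway of DNA crosslink repair, rose from 0.955 ± 0.165 to 15.4 ± 3.90 CPM (adjusted p = 0.00884). PDE5A, a cyclic GMP phosphodiesterase, rose to 16.9 ± 3.41 CPM, the magnesium channel TRPM6 to 13.1 ± 1.53 CPM and FPGS, which adds glutamates to folates, to 69.0 ± 32.4 CPM, from WT means of 2.29, 2.05 and 11.6 CPM. G0S2, an inhibitor of triglyceride breakdown, fell from 69.8 ± 20.7 to 7.64 ± 2.02 CPM (adjusted p = 0.0241). METTL21B fell by 1.29 (SE 0.18) and GOLT1A by 1.14 (SE 0.16) on the log2 scale.

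Gene lists held few called members in FA. Of 21 p53 response genes 1 rose, TIGAR, from 0.730 ± 0.331 to 5.18 ± 1.62 CPM (5 when adjusted over the list alone; camera adjusted p = 2.43e-06, and adjusted p = 0.047 with an estimated correlation, or 0.168 without FK replicate 3, with a list median of 0.52 in both fits). Fetal liver genes (1 of 13 higher, GPC3; 4 when adjusted over the list alone) and NRF2 and glutathione genes (0 of 19; 2 higher when adjusted over the list alone) ranked higher by camera. Their adjusted p were 0.000369 and 0.00255, and adjusted p = 0.31 and 0.235 with an estimated correlation. NQO1, the first of the NRF2 members, stood at 1.79 log2 units above WT (SE 0.27, adjusted p = 0.0514). Markers of endothelial, stellate, cholangiocyte, macrophage, and B and plasma cells and the collagen list ranked lower, with list medians between -1.5 and -0.46 and no member called over all genes. Adjusted over the list alone, 4 endothelial and 3 macrophage markers were lower and no member of the other 4. Their camera adjusted p ran from 4.3e-07 to 0.00774, and from 0.133 to 0.31 with an estimated correlation. Their members with the smallest p were CDH5, PDGFRA, SOX9, C1QC, MS4A1 and COL6A2, all at adjusted p of 0.244 or more. Cholesterol synthesis (0 of 19 called, 9 lower when adjusted over the list alone), lipid synthesis (0 of 14 and 0) and tyrosine breakdown (FAH alone of 8, also over the list alone) ranked lower too, with camera adjusted p of 1.93e-06, 0.00478 and 0.00117. With an estimated correlation they had adjusted p = 0.367, 0.31 and 0.133. HMGCS1 and GPAM led the first 2 lists at -2.37 and -1.59 (adjusted p = 0.224 and 0.324). The tyrosine breakdown median was only -0.18, with FAH at -3.37. That list was not tested without FAH, so its camera call does not show that the rest of the pathway was lower in FA. In all, 12 of 35 lists were called, 3 up and 9 down. The 25 calls became 2, 7 and 2 without WT replicates 1, 2 and 3, 6, 16 and 4 without FA replicates 1, 2 and 3, and 11, 13 and 247 without FK replicates 1, 2 and 3. DESeq2 called 342.

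Most genes called between FA and WT were also called between FK and WT, to an extent that varied with the fit. Of the 25 calls in FA, 24 were calls in FK with the same direction, 14 higher and 10 lower, against 0.425 and 0.19 expected for independent lists. The lists are not independent, so that expectation is not a fair standard. Both comparisons use the same WT replicates and, for each gene, 1 spread estimated over all 9 replicates. In 20 simulations all 9 replicates, WT included, were drawn without any change from 1 mean and 1 spread per gene. The simulated FA and FK groups, set against the same simulated WT replicates, shared 0 calls in each. They held at most 1 call in either comparison, so that 0 sets no bound on the overlap. TIGAR, SCG3, FANCD2, GPC3, PDE5A, TRPM6, FPGS, G0S2, METTL21B and GOLT1A were among the 24. Over all genes, log2 changes of FA and FK correlated at r = 0.475 against a simulated 0.5, and their covariance was 0.521 against 0.18. The simulated covariance already holds what the shared WT replicates give at the simulated spread. With 3 WT replicates the controls could not be split into parts of at least 2, so a larger part from shared controls than simulated stays open. The overlap was 244 of the 342 FA calls with DESeq2 and 260 of 440 with limma-voom. It was 26 of 235 with only the 2 groups compared, where each comparison had its own spread and FK and WT gave just 43 calls. Without WT replicates 1, 2 and 3 the overlap was 2 of 2, 7 of 7 and 2 of 2. Without FA replicates 1, 2 and 3 it was 6 of 6, 16 of 16 and 4 of 4. Without FK replicates 1 and 2 it was 11 of 11 and 13 of 13, and without FK replicate 3 it was 139 of 247.

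The comparison of FA with FK asked whether the livers labelled FA differed from those labelled FK. No gene reached an adjusted p under 0.05 in edgeR, with 3275 at an unadjusted p under 0.05, and so none reversed a change of FK from WT. DESeq2 called 1778 genes, of which 1178 reversed such a change. Without FK replicate 3, edgeR called 5324, 2531 higher and 2793 lower in FA, and 4081 reversed a change. Among the 712 genes called between FK and WT, 665 had FA on the same side of WT as FK and 418 had FA nearer to WT than to FK, with a median FA change of 43.6% of the FK change. These genes were selected for a large change in FK, which by itself lowers that ratio. Both changes were taken against the same WT replicates, which by itself puts FA on the side of FK and raises the ratio. Changes of simulated unchanged groups correlated at r = 0.5. Neither the 665 nor the 43.6% was set against a value for unchanged groups, so they do not show how far FA shares the FK changes.

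Of 9 of the 16 lists called between FA and FK, 5 set FK replicates 1 and 2 apart from FA and not FK replicate 3. These 9 are not the 9 with the smallest camera adjusted p, since the collagen list (2.76e-06), given with the others below, ranked ahead of some of them. Erythroid (median log2 difference -6.85), neutrophil (-4.77) and cell division (-3.83) lists ranked lower in FA by camera, with adjusted p of 9.93e-09, 2.14e-06 and 4.17e-15. Drug metabolism (1.5), interferon response (1.24), cholesterol synthesis (1.06), bile acid (1.12), tyrosine breakdown (0.88) and T and NK cell lists (1.31) ranked higher, with adjusted p from 4.73e-09 to 0.00671. None of these 9 lists had a member called over all genes. Adjusted over the list alone, 15 of 16 erythroid, 9 of 10 neutrophil and 29 of 30 cell division genes were lower and 10 cholesterol, 6 tyrosine breakdown and 4 T and NK genes were higher. Also over the list alone, 1 tyrosine breakdown, 1 T and NK and 1 bile acid gene were lower, and no drug metabolism or interferon gene passed. Each of these 9 lists had adjusted p = 0.342 with an estimated correlation. The member with the smallest p was SPTB for erythroid, S100A9 for neutrophil, KIF20A for cell division, CYP2B4 for drug metabolism and MX1 for interferon genes, all at adjusted p of 0.115 or more. Over all 35 lists camera called 16, 8 up and 8 down. The erythroid, neutrophil, cell division, drug metabolism and interferon medians of FK replicate 3 (-1.16, 0.12, 0.28, -0.14 and -0.41 from WT) lay within the FA ranges of -1.43 to -0.66, -0.10 to 0.55, 0.10 to 0.56, -0.15 to -0.05 and -0.57 to 0.49. Those for tyrosine breakdown (-0.74), cholesterol synthesis (-1.68), bile acid genes (-0.42) and T and NK cells (-1.24) lay below the FA ranges of -0.29 to -0.08, -1.5 to -0.44, -0.36 to 0.09 and -0.81 to 0.06. Without FK replicate 3, 11 of the 16 lists were called, and not tyrosine breakdown (0.0804), NRF2 (0.0804), T and NK (0.054), lipid synthesis (0.109) and acute phase (0.316). The medians of those 5 were 1.15, 0.75, 1.85, 0.68 and -0.43 there, against 0.88, 0.94, 1.31, 0.76 and -0.54 with FK replicate 3. Complement (median 0.56, adjusted p = 0.021) and integrated stress genes (-0.61, 0.00322) were called there in addition. With an estimated correlation, drug metabolism alone passed there (0.00293).

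A further 7 lists were called between FA and FK. Collagen and matrix genes (median -0.74; 12 of 32 lower when adjusted over the list alone), macrophage markers (-0.57; 5 of 16), glycolysis genes (-0.44; 6 of 21), acute phase genes (-0.54; 0 of 18) and fetal liver genes (-1.49; 6 lower and 1 higher of 13) ranked lower in FA. NRF2 and glutathione genes (0.94; 0 of 19) and lipid synthesis genes (0.76; 5 higher and 1 lower of 14) ranked higher. Camera's adjusted p ran from 2.76e-06 for the collagen list to 0.0462 for the fetal liver list. With an estimated correlation, adjusted p = 0.342 for the collagen, macrophage, NRF2 and lipid lists and 0.465 for the other 3. No member was called over all genes, and those with the smallest p were COL12A1, the scavenger receptor CD163, PFKFB3, LCN2, IGF2BP3, NQO1 and ACACB, at adjusted p of 0.115 to 0.127. The fetal liver median of FK replicate 3, at 0.20 from WT, lay near the FA range of 0.27 to 0.48, against 1.98 and 3.54 in FK replicates 1 and 2. The collagen median was 0.21, 0.55 and -0.54 in FK replicates 1, 2 and 3, the last within the FA range of -0.91 to -0.48. Glycolysis stood at 0.89, 1.01 and -0.12, against -0.08 to 0.14 in FA, and macrophage markers at 0.25, 0.02 and -0.20, against -0.77 to -0.41.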

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

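The tests of a swap and of a wrong label below, and the count of lists, were chosen only after the result was seen. In each of the 9 sets of 4 libraries, FAH level, albumin share and other library measures were examined for a library far from the other 3. Among 36 such tests 2 stood out, and chance gives about 1 in 20. FAH was 17.91 per M counts, before TMM scaling, in library 4 of FK replicate 3, against 12.22 to 12.82 in the other 3 libraries of that set. Albumin took 12.87% of the counts in library 4 of FK replicate 1, against 16.27% to 16.65% in the others. No explanation was tested for either.

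FK replicate 3 stood apart from FK replicates 1 and 2, but if it had been swapped with an FA replicate, an FA replicate would lie near FK replicates 1 and 2, and 0 of the 3 FA replicates correlated better with those than with each other, which argues against a swap. Depth is argued against too, since after thinning every replicate to 53156924 counts the lowest correlation with FA still exceeded the highest with FK by 0.103 (0.958 against 0.855). An FA replicate under a wrong label cannot be told apart from an FK replicate that differed, because FAH in FK replicate 3 lay 2.69 SD of the 3 FA replicates below the FA mean (-2.69), between the 2 bounds set for that test. At 14.6 CPM it lay between FK replicates 1 and 2 (16.4 and 11.8) and below the lowest FA replicate (19.6). Among 35 lists the median of FK replicate 3 lay outside the range of the 3 FA replicates in 22, where exchangeable replicates give 50%, for example at -0.74 against -0.29 to -0.08 for tyrosine breakdown and at -1.02 against -0.81 to -0.35 for lipid synthesis, but the lists are not independent and do not settle it. A biological difference among the FK livers stays open as well and may be its source, untested, since the labels give nothing that parts the FK sets.

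The number of genes called was compared with all 10 splits of the 6 replicates into 3 and 3, whose share can never be under 0.1. FK and WT gave 712 calls in the real split and at most 0 in the others, so 1 of 10 reached the real count. FA and WT gave 25 and at most 1, again 1 of 10. FA and FK gave 0 calls in the real split by edgeR (3275 at an unadjusted p under 0.05; 1778 by DESeq2) and at most 1 in the others. All 10 reached a count of 0, as any split must, so this says nothing about that comparison.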

How the results depend on the processing

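The spread between 3 replicates and the position of FK replicate 3 limited the counts of calls more than scaling or filters did, and 2-fold changes were mostly below what the self-test recovered. With RLE size factors, either filter on low counts or a 2-fold minimum, each count of genes stayed within 1.5 times its reported value, and scaling moved the median log2 change over all genes by under 0.1. FAH was lower in FK and in FA than in WT at an adjusted p under 0.05 in all alternatives. The cause of the differences below was not tested unless stated.

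Genes called between FK and WT (712) numbered 2721 with DESeq2, 43 with only the 2 groups compared, 7372 with 36 libraries as separate replicates, 2448 with limma-voom with the set as a random block, 189 with library 1 of each set only, and 22 (without FK replicate 1) to 5396 (without FK replicate 3) in leave-one-out. Between FA and WT (25) they numbered 342 with DESeq2, 235 with only the 2 groups compared, 4330 with 36 libraries, 440 with limma-voom, and 2 (without WT replicate 1 or 3) to 247 (without FK replicate 3) in leave-one-out. Between FA and FK (0 by edgeR, 3275 at an unadjusted p under 0.05) they numbered 1778 with DESeq2, 6984 with 36 libraries, 2169 with limma-voom, and 0 to 5324 in leave-one-out, where FK replicate 3 alone gave more than 0. Treating 36 libraries as replicates counts the libraries of a set as independent, which raises calls by construction.

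Genes changed in both FA and FK (24) numbered 244 with DESeq2, 2519 with 36 libraries, 260 with limma-voom, and 2 (without WT replicate 1 or 3) to 139 (without FK replicate 3) in leave-one-out. Genes that reversed between FA and FK (0) numbered 1178, 4859 and 1391 with the same 3 alternatives, and 0 to 4081 in leave-one-out, the last without FK replicate 3. The FAH difference between FA and FK (0.71) passed with DESeq2 (0.73) and 36 libraries (0.702); leave-one-out values ran from 0.6 (without FK replicate 2) to 0.836 (without FA replicate 3), and passed without FK replicate 3 (0.748).

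With an inter-gene correlation estimated per list, 0 of 15 lists were called between FK and WT, 1 of 12 between FA and WT and 0 of 16 between FA and FK. Fry called 11, 4 and 1, of which 8, 4 and 1 were among camera's. Between FK and WT it did not call cell division (adjusted p = 0.105), erythroid (0.138), neutrophil (0.12), drug metabolism (0.0728), interferon (0.105), acute phase (0.128) or complement genes (0.265). In leave-one-out the counts were 15 to 17, 11 to 15 and 13 to 19. Of 54 results for named genes other than FAH, 50 were calls. Of these, 30 to 46 were lost without 1 replicate other than FK replicate 3, 0 without FK replicate 3, 42 with the replicate block, 33 with only the 2 groups compared, 23 with library 1 of each set only, 5 with limma-voom and 1 without a filter. Without FK replicate 3 the fitted change of 8 of 41 called genes named between FK and WT was over 1.5 times larger and of 0 smaller: KMO 348-fold, CYP7A1 210-fold, KRBOX1 37.2-fold, GPAM 15.9-fold, CYP27A1 8.56-fold, CD5 8.22-fold, CYP2J1 6.82-fold, and ADCY8, which rests on few counts. Without FK replicate 2 it was larger for 0 and smaller for 8, in log2 AFP (7.77 against 8.85), CCNE1 (2.97 against 4.29), DUSP9 (6.07 against 7.14), KIF20A (3.62 against 4.53), IGF2BP3 (3.67 against 4.40), S100A8 (5.12 against 5.78), S100A9 (5.40 against 6.11) and ADCY8. It was smaller for NRK without FK replicate 1 (9.16 against 9.80). Without WT replicate 1 it was larger for CYP19A1, DUSP9 and ELOVL4 and smaller for SERPINB7, which was larger without WT replicate 3. No such move came without WT replicate 2 or an FA replicate, nor for the 11 named genes called between FA and WT. These 11 and the 41 above include FAH.

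The sets share only a number. Same-number replicates of different groups correlated at r = -0.087 to 0.099 after group means were removed, and 3 of 9 correlated best with their own number. The replicate block gave 47 calls between FK and WT, 3 between FA and WT, 3 in both, and 0 between FA and FK.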

Other observations

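The tests of hepatocyte share and of circulating blood below, and the choice of genes outside the naming rule, were made only after the results were seen. Lists that camera did not call between FK and WT still held called genes. CD163, a scavenger receptor of macrophages, was 1 of 16 macrophage markers called and rose by 6.54 log2 units (SE 1.20, adjusted p = 0.0355), and APOA1, the main protein of high-density lipoprotein, was 1 of 20 hepatocyte secreted protein genes called and rose by 5.59 (SE 1.13, adjusted p = 0.0404). MTHFD2, of mitochondrial folate metabolism, rose by 4.99 in the integrated stress list (2 of 21 higher), ME1 by 2.88 in the NRF2 list (1 of 19) and COL12A1 by 2.19 in the collagen list (2 of 32). SOX9 fell by 1.90 among cholangiocyte markers (1 higher and 1 lower of 14), EHHADH by 1.88 among fatty acid oxidation genes (1 lower of 23), CLEC4G by 1.43 among endothelial markers (1 lower of 15), CDH16 by 5.73 among kidney tubule markers (1 lower of 6) and NR1H3 by 1.32 among liver transcription factors (1 lower of 17). PPARGC1A rose by 1.37 among gluconeogenesis genes (1 of 15) and PFKFB3 by 1.51 among glycolysis genes (1 higher and 1 lower of 21; 9 higher and 1 lower when adjusted over the list alone). The changes of CDH16 and ME1 were -6.39 and 2.20 without FK replicate 3, and that of MTHFD2 was 4.04 without FK replicate 2. Adjusted over the list alone, the counts were 5 higher for integrated stress, 3 higher for collagen, 2 higher and 2 lower for cholangiocyte, 2 lower for transcription factor and 1 higher and 1 lower for gluconeogenesis genes, and, glycolysis aside, unchanged for the other lists named. No member was called of the heme synthesis (2 higher and 1 lower when adjusted over the list alone), urea cycle (1 lower), immediate early (2 higher), stellate cell, oxidative phosphorylation, inflammatory or ribosomal protein lists (0 also over the list alone for these 4; 4016 genes had an unadjusted p under 0.05, and DESeq2 called 2721).

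Some genes had counts on 1 side of the WT comparison alone. LOC103345889 stood at 7.73 CPM in WT and had 0 counts in FA and FK, at least 494-fold and 488-fold lower, and LOC100353012 had 0 counts in WT and was at least 121-fold higher in FA and 93-fold higher in FK. GABRG1, a receptor subunit, was the 1 gene called between FA and WT but not between FK and WT, at 2.29 ± 0.645 CPM in WT, 0.0574 ± 0.0257 in FA and 0.540 ± 0.309 in FK.

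Erythroid, neutrophil and cell division lists had high medians in FK replicates 1 and 2 and not in replicate 3, except for genes such as TFRC (143 CPM in replicate 3 against 23.9 in WT) and TYMS (7.28 against 1.87). A lower share of hepatocytes would raise the markers of other cell types alike. However, 71 markers of 5 other lists (endothelial, stellate, cholangiocyte, T and NK, B and plasma cells) had a median log2 difference of -0.61 (quartiles -1.7 to 0.05). For 26 erythroid and neutrophil markers it was 4.37 (2.47 to 6.09). Macrophage markers, left out of the 71, had a median of 0.04, and 26 of the 71 are the lymphocyte markers used next. Circulating blood would bring lymphocytes, whose 26 T, NK, B and plasma cell markers had a median of -1.74 (-2.25 to -1.23). These markers were also low in FK replicate 3 (medians of -1.24 for T and NK and -1.73 for B and plasma cells), where the erythroid median was -1.16. A fall unrelated to the erythroid rise could hide lymphocytes brought by blood, so these values cannot decide on circulating blood. Genes of early blood-forming cells had a median of 4.03 (MYB 4.73, TAL1 4.62, NFE2 5.05, KIT 3.44, GATA2 2.09 and LMO2 -0.70), none of them called singly (GFI1B was listed but not tested) and all but LMO2 high in FK replicates 1 and 2 alone (TAL1 35.2, 94.1 and 0.98 CPM in replicates 1, 2 and 3), so blood-forming cells in the livers of those 2 replicates are a candidate explanation. The ages of the animals are not in the labels, so an age difference, which could part livers by blood formation, stays open and untested.

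Of the 25 genes called between FA and WT, 24 were called the same way between FK and WT. Shared WT replicates, and the estimate of spread that both comparisons share, stay open as sources of part of this overlap. The largest overlap of 20 simulations was 0, but the simulated groups held at most 1 call to share. Genes that neighbour FAH, which could be inherited with it, held 0 of the 19 other shared calls with a known place among the 100 tested genes nearest FAH. Only 0.14 were expected there by chance (Fisher p = 1), so that test could exclude a cluster but not a few linked genes farther away. A difference in strain or descent between WT and the other 2 groups may also underlie genes with 0 counts on 1 side, which was not tested.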
